A study of Mus musculus with 4 samples.

How the data were processed

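Single-cell RNA libraries of the adult mouse small-intestinal epithelium were made with inDrop v2, per the labels' protocols, from cells sorted as EpCAM-positive and negative for CD45, TER119 and DAPI, with 5000 sorted cells per condition. The labels give 2 control libraries, from mice with loxP-flanked Lats1 and Lats2 and no Cre, and 2 Lats-deleted libraries, from mice that also carried the tamoxifen-inducible Cre recombinase Lrig1-CreERT2. Both groups received 2 mg of tamoxifen by intraperitoneal injection and were taken at day 7. The labels do not say whether each library is a separate animal, so p-values measure the spread between these libraries.

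The deposited values are counts, one file per library, with a barcode per line and a gene symbol per column, per the file headers. All values were found to be whole numbers of at least 0, and the file totals differ between libraries, so they are taken as counts that were not normalized. Bowtie 1.1.1.1, SAMtools 1.3.1, RSEM 1.3.0 and the genome build mm10 are named without a role or order, per the submitters' processing notes. Whether the counts are of molecular identifiers is not stated, so they are called counts here, and intervals cover counting error only. All 4 files hold the same 25289 gene columns, of which 24601 (97.3%) match a symbol of the GENCODE M21 annotation on GRCm38, the assembly of mm10. Coordinates are given from that annotation. Epcam, Mki67 and some further listed genes have no column under the symbols used and are not analysed here.

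A barcode was kept as a cell with at least 1000 counts, at least 300 genes and at most 30% mitochondrially encoded counts. Kept cells were scaled to 10000 counts and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours gave Leiden clusters at a resolution of 1 (scanpy 1.11.5, leidenalg 0.10.2, seed 1). A cluster took the name of the marker list with the highest mean log2 fold change, if 3 conditions held. At least 3 markers were 1.5-fold above the other cells and detected in 10% of its cells, and the mean was above 0.5. No other list had more members among the 10 genes of highest fold in the cluster. A cluster with far fewer counts per cell than its libraries and no own marker among these 10 genes also stayed unnamed. Names end in "-like" because they rest on markers. Clusters rest on genes that differ between the groups, so their sizes are described and not tested further. Scrublet, with an expected share of 5%, called 3, 8, 0 and 4 doublets in the 4 libraries, which is few for this number of cells.

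The library was the unit of replication. Counts of the cells of a library were summed over all kept cells, over stem-like and cycling progenitor-like cells, and over enterocyte-like cells, where each library held at least 20 such cells. Genes were filtered with filterByExpr, scaled with TMM and tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3). An adjusted p (Benjamini-Hochberg) under 0.05 was the threshold. CPM were computed by edgeR with the TMM-scaled library size. CPM of a gene list, or of a gene within a cluster or a set of barcodes, use the plain total of the counts summed. Log2 fold changes are Lats-deleted over control. A gene at 0 in both libraries of a group has a fold given as a lower bound, the lower of the mean CPM and the CPM of the summed counts in the other group over the CPM of 3 counts in the group at 0. A gene with 1 to 3 counts has a ratio of summed counts over summed TMM-scaled sizes with a 95% counting interval. The difference of the Lats effect between the progenitor and enterocyte-like classes was tested as the class by genotype term with the library as a block. Shares of cells were compared with a two-sided exact permutation test over the 6 splits of the 4 libraries, whose smallest p is 0.333, and each share has an exact (Clopper-Pearson) 95% interval. Where a share of 0 is said to allow a share, that limit is 3 counts over the number of cells. For shares of cells with a count of a gene, each cell was first thinned to 1000 counts.

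Before the data were examined, 27 gene lists, 10 marker lists and a rule for the genes to name were fixed. The lists hold YAP and TAZ targets, Hippo components, fetal-like and regenerative genes, Lgr5 stem cell genes, Wnt targets, cell division, enterocyte, villus tip, villus bottom, goblet, Paneth, enteroendocrine, tuft, proximal, ileal, colon, leukocyte, stromal and endothelial, erythroid, interferon response, MHC class II, antimicrobial, p53 target, immediate early and heat shock, cholesterol synthesis, mitochondrially encoded, and keratin and actin genes. The rule names Lats1, Lats2 and Lrig1, then the 8 largest increases and 8 largest decreases past the threshold with at least 20 CPM in the higher group and no overlap of the groups, leaving out predicted gene models, and up to 4 members of each list with the smallest p. Some results for genes withheld for evaluation are not reported here. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. At an estimated correlation camera rests on the few degrees of freedom left by 4 libraries, so few lists could pass. Lists of stomach genes, Y-linked genes, pancreatic enzyme genes and intestinal transcription factor genes were added after values had been seen.

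The gene tests, the class by genotype term and camera were tested on simulated counts drawn from the means and sizes of these libraries, with 200 genes changed by known folds. At 4-fold edgeR recovered 72.6% of the changed genes in the all-cell design of 12619 genes, 70.4% in the progenitor design of 5013, 45.9% in the enterocyte-like design of 5735 and 17.7% for the class by genotype term with 5464 genes. At 2-fold it recovered 1.52%, 8.47%, 1.59% and 1.67%. Unchanged genes made up 2.13%, 4.35%, 3.33% and 0% of the calls. In all but the enterocyte-like fit, far more genes passed in the data than in these simulations, so the recovered shares describe the simulated setting only. A shifted list was called by camera in each of the 3 classes, and 0 of 24 unshifted lists were called in each. Genes were drawn independently there, so false calls were not tested for lists whose members vary together. The estimated correlation reached 0.956 for MHC class II genes in all cells.

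The alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, minimums of 500 and 2000 counts per cell, other mitochondrial limits, no called doublets, thinned libraries, a replicate term, classes from marker scores, a Leiden resolution of 2, and each library left out in turn. Without 1 library of a group, the remaining library is assumed to vary like the other group. Whether replicate numbers pair the libraries is not known. The within-group differences correlate across genes at r = 0.0468, which gives no sign of pairing but cannot exclude it. The replicate term is therefore only an alternative. A fit without leukocyte-like and stromal-like clusters was also planned. Fits without clusters in which the stomach list exceeds 2000 CPM, alone or together with stromal-like cells, and without genes of chromosomes X and Y were added after the data were seen.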

Results

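Messenger RNA was counted in single cells of the adult mouse small-intestinal epithelium with inDrop, a droplet method that barcodes the transcripts of each cell. The 4 libraries form 2 groups of 2, control and Lats-deleted, taken at day 7 after tamoxifen. LATS1 and LATS2 are the kinases of the Hippo pathway that hold back the transcriptional coactivators YAP and TAZ, and the comparison asks how the epithelium differs after their deletion from Lrig1-expressing cells. Control libraries 1 and 2 hold 2872497 and 2247269 counts, and Lats-deleted libraries 1 and 2 hold 4731529 and 9191916. Kept cells numbered 774 and 515 in the control libraries and 726 and 1289 in the Lats-deleted libraries. Their median counts per cell were 1708 and 1995 against 3715.5 and 3848, and their median mitochondrially encoded shares were 9.55% and 6.84% against 3.64% and 3.90%. Log CPM correlated across genes at r = 0.955 between the control libraries, at 0.941 between the Lats-deleted libraries and at 0.678 to 0.698 between groups, where genes are not independent replicates. Sex-linked genes also split the groups. Xist, which female cells express, was at 9.35 and 6.51 CPM in the control libraries and at 640 and 505 CPM in the Lats-deleted libraries, and the Y-linked genes were at 93.5 and 108 against 34.8 and 25.4 CPM.

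Of the targeted genes, Lats1 (ENSMUSG00000040021.13, chromosome 10, 7681214 to 7716460 on GRCm38) was lower after deletion, at 29.3 ± 8.34 CPM in controls and 8.09 ± 1.65 CPM in Lats-deleted libraries (SD, n = 2 each). Its log2 fold change was -1.83 (SE 0.347, adjusted p = 0.0087), with adjusted p between 1.82e-06 and 0.0871 over the alternatives and a call lost without control library 2, at 0.0871. Lats2 (ENSMUSG00000021959.16, chromosome 14, 57689662 to 57758388) was higher, at 9.88 ± 0.9496 CPM in controls and 23.7 ± 4.99 CPM after deletion, a log2 fold change of 1.26 (SE 0.335, adjusted p = 0.0305). The Lats2 call was lost with DESeq2 and without either control library, with adjusted p between 0.000801 and 0.178 over the alternatives. Lrig1, the site of the Cre driver, was at 17.3 ± 0.415 and 13.0 ± 1.65 CPM (log2 fold change -0.41, adjusted p = 0.357). The labels do not give the deleted exons and the assay reads the 3' end, so these values check the labels little.

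In the sum of all kept cells, the Lats-deleted libraries had high levels of fetal-like and regenerative genes and low levels of enterocyte and goblet genes. Clusterin (Clu, ENSMUSG00000022037.15, chromosome 14, 65968483 to 65981547), a marker of regenerating crypt cells, rose from 7.85 ± 0.0864 to 4481 ± 193 CPM (SD, n = 2 each), a log2 fold change of 9.15 (SE 0.320, adjusted p = 0.000183). Ly6a, the gene of the antigen Sca-1, was at 2.12 and 0 CPM in the control libraries and at 2186 and 1015 CPM in the Lats-deleted libraries, a ratio of 1249 (95% counting interval 427 to 6055). Mesothelin (Msln) was at 1.42 and 0 against 2248 and 988 CPM, a ratio of 1882 (521 to 15550). Mal, a membrane-trafficking proteolipid, was at 0 in both control libraries and at 786 and 619 CPM after deletion, at least 581-fold higher.

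Altogether 3869 of 12561 genes tested passed the threshold, 1923 higher and 1946 lower in the Lats-deleted libraries, and 5350 had an unadjusted p under 0.05. The groups did not overlap in 68.8% of the genes, where chance gives 33.3%. The 8 largest increases named by the rule were Mal, Spp1, Msln, Try5, Ly6a, Ly6k, Fam46b and Clu. Spp1 (at least 71.9-fold higher) and Ly6k (at least 41.8-fold) were mostly in Lats-deleted library 2, at 159 and 90.6 CPM there and at 10.3 and 7.70 CPM in library 1. Cluster 5, a cluster with high counts of stomach genes, held 43.5% and 39.1% of their counts in library 2. Both calls were lost with at least 2000 counts per cell, at adjusted p of 0.0661 and 0.05, and without either control library. Fam46b, at 0 in the controls, was at least 26.1-fold higher. Try5, a trypsinogen of the pancreas, was at least 49.1-fold higher, but 2 cells of library 1 and 1 cell of library 2 held 90% of its counts. The 8 largest decreases were Mptx1, Ugt2b5, Cyp3a41a, Cyp3a41b, Leap2, Zg16, Hsd17b6 and Cyp3a11. Zg16, a lectin of goblet cell granules, went from 11160 and 20330 CPM to 17.2 and 345 CPM, with a log2 fold change of -6.44 (SE 1.34, adjusted p = 0.0123) and a call lost without either control library, at adjusted p up to 0.0815. Cyp3a11, a drug-metabolising cytochrome P450 of enterocytes, fell by 6.22 on the log2 scale (SE 0.450, adjusted p = 0.000275). Cyp3a41a and Cyp3a41b have near-identical sequences, so their counts cannot be told apart with certainty. Without control library 1 the count of genes was 1228, without control library 2 it was 1478, and without Lats-deleted library 1 or 2 it was 5387 or 5012.

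**Figure D1:**
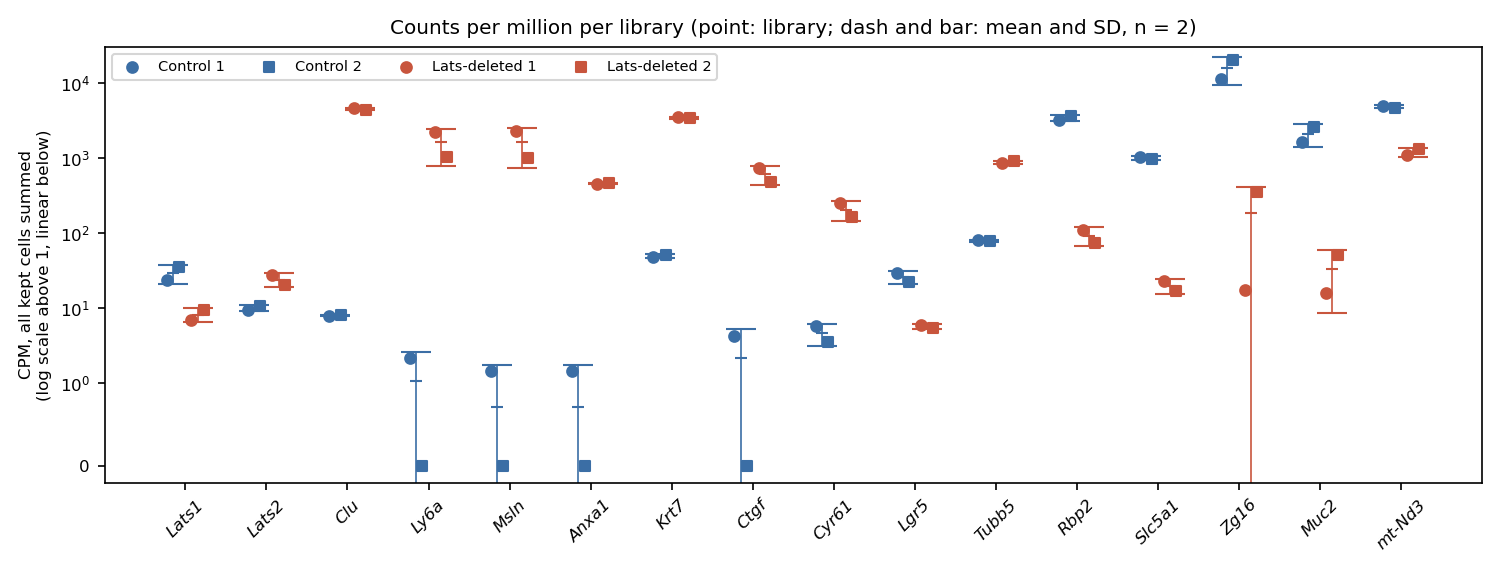
CPM of 16 genes (axis logarithmic above 1 and linear below) in each of the 4 libraries, summed over all kept cells; circles and squares are libraries 1 and 2 of the control (blue) and Lats-deleted (red) groups, and dashes with bars are means with SD (n = 2). Clu is at 7.79 and 7.91 CPM in the controls and at 4618 and 4345 CPM in the Lats-deleted libraries, and Slc5a1 at 1032 and 954 against 22.8 and 16.6.

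All 26 tested members of the fetal-like and regenerative list rose, and 26 also when adjusted over the list alone, with a median log2 fold change of 5.23 (camera adjusted p = 2.66e-16, adjusted p = 0.272 with an estimated correlation). The list's share of all counts was 0.129% in both control libraries and 3.89% and 3.11% in the Lats-deleted libraries. Annexin A1 (Anxa1) had a ratio of 580 (160.5 to 4792), Anxa8 a log2 fold change of 7.78 (SE 0.386, adjusted p = 0.000183), and keratin 7 (Krt7) one of 6.12 (SE 0.273, adjusted p = 0.000183). Of 20 YAP and TAZ target genes, 13 rose and 1 fell, 14 and 1 when adjusted over the list alone, with a median of 3.32 (adjusted p = 8.3e-06, adjusted p = 0.38 with an estimated correlation). Among them the matricellular genes Ctgf and Cyr61 had log2 fold changes of 7.997 and 5.43, where Ctgf had 6 counts in control library 1 and 0 in library 2 and ran from 7.15 to 14.13 over the alternatives, and the coagulation initiator F3 and the ferlin Myof 6.47 and 5.23. Ctgf, Cyr61 and Fam46b stand in the files under older symbols and have no coordinates in the annotation used. Of 19 Hippo pathway components, 11 rose and 1, Lats1, fell, 12 and 1 when adjusted over the list alone, with a median of 1.26 (adjusted p = 0.000143, adjusted p = 0.38 with an estimated correlation). Wwtr1, which encodes TAZ, rose by 4.39 on the log2 scale, its DNA-binding partner Tead1 by 3.30, and Wwc1, an upstream activator of LATS, by 2.38. Keratin and actin cytoskeleton genes rose in 16 of 19 members, with 17 higher and 1 lower when adjusted over the list alone and a median of 2.22 (adjusted p = 7.13e-09, adjusted p = 0.272 with an estimated correlation). Filamin A (Flna) had a log2 fold change of 5.64 and the actin cross-linker Actn1 one of 4.05.

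Most genes of the enterocyte list fell. Of 28 enterocyte genes, 26 fell, 27 when adjusted over the list alone, with a median log2 fold change of -5.13 (camera adjusted p = 2.67e-18, adjusted p = 0.38 with an estimated correlation). The sodium-glucose transporter Slc5a1 fell by 5.66 on the log2 scale (SE 0.297, adjusted p = 0.000183), the glucose transporter Slc2a2 by 5.46 and lactase (Lct) by 5.17. Enterocyte-like cells also made up a much smaller share of the Lats-deleted libraries. Proximal small intestine genes fell in 9 of 11 members, 9 also when adjusted over the list alone (median -4.56, adjusted p = 1.25e-06, adjusted p = 0.38 with an estimated correlation). Retinol-binding protein 2 (Rbp2) had a log2 fold change of -5.22 and Adh6a one of -5.48. Ileal genes fell in 4 of 7, 4 when adjusted over the list alone (median -2.39, adjusted p = 0.0203, adjusted p = 0.38 with an estimated correlation), and Mep1b had a log2 fold change of -5.35. The 3 colon genes with enough counts, among them Slc26a3 with a log2 fold change of -5.54, also fell, 3 when adjusted over the list alone, and were too few for a list test. Villus bottom genes fell in 6 of 9 members, 6 when adjusted over the list alone (median -2.08, adjusted p = 0.000876, adjusted p = 0.46 with an estimated correlation). The chemokine Ccl25 had a log2 fold change of -5.07 and Reg1 one of -5.30. Of 12 villus tip genes 3 rose and 4 fell, 4 and 5 when adjusted over the list alone (median -0.04, adjusted p = 0.82), among them Egfr with a log2 fold change of 1.96 and the adenosine deaminase gene Ada with -4.63.

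Of the secretory lists, the goblet, Paneth and tuft lists were lower by camera at the preset correlation and the enteroendocrine list did not pass. Of 17 goblet cell genes, 14 fell, 14 when adjusted over the list alone, with a median log2 fold change of -4.21 (camera adjusted p = 1.58e-07, adjusted p = 0.38 with an estimated correlation). The mucin Muc2 went from 1599 and 2576 CPM to 15.7 and 50.7 CPM, a log2 fold change of -5.96 (SE 0.638, adjusted p = 0.000942), and Spink4 had one of -5.65. Of 13 Paneth cell genes, 9 fell, 10 when adjusted over the list alone (median -4.01, adjusted p = 2.06e-05, adjusted p = 0.38 with an estimated correlation), and the defensin gene Defa5 had a log2 fold change of -4.75, with all of its control counts in 2 cells of library 1 and 1 cell of library 2. Tuft cell genes fell in 6 of 14 members, 8 when adjusted over the list alone (median -2.17, adjusted p = 0.00271, adjusted p = 0.517 with an estimated correlation). Kctd12 had a log2 fold change of -2.96. Of 14 enteroendocrine cell genes 1 fell, the secretin gene Sct, and 0 when adjusted over the list alone (median -0.61, adjusted p = 0.102). Sct had a log2 fold change of -2.28 (SE 0.559, adjusted p = 0.0226), a call lost without control library 2, at 0.111, with adjusted p from 6.23e-24 over the alternatives.

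The Lgr5 stem cell list was not called as a whole in the sum of all cells, where its share of counts was 0.0662% and 0.0779% in the controls and 0.152% and 0.134% after deletion, with 5 of 23 members higher and 5 lower, 5 and 5 when adjusted over the list alone (median 0.28, camera adjusted p = 0.823). Lgr5, the receptor that marks crypt base stem cells, fell by 2.18 on the log2 scale (SE 0.330, adjusted p = 0.00362), from 29.0 and 21.97 to 5.90 and 5.36 CPM, a call lost without control library 1, at 0.0571, with adjusted p from 5.67e-07 over the alternatives. The water channel Aqp4 fell by 2.81, whereas Cd44 and Cdk6 rose by 2.82 and 3.08. Of 14 Wnt target genes 4 rose and 4 fell, 4 and 5 when adjusted over the list alone (median 0.50, adjusted p = 0.819). Cyclin D1 (Ccnd1) had a log2 fold change of 3.98 (SE 0.252, adjusted p = 0.000202) and the transcription factor Sp5 one of -2.67 (SE 0.321, adjusted p = 0.00148). Of 28 cell division genes 6 rose and 0 fell, 3 and 0 when adjusted over the list alone (median 1.18, adjusted p = 0.00101, adjusted p = 0.651 with an estimated correlation). The tubulin Tubb5 had a log2 fold change of 3.47.

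Stress-related lists were higher by camera at the preset correlation, but p53 target genes did not pass with fry (adjusted p = 0.0774). Immediate early and heat shock genes rose in 14 of 20 members, with 15 higher and 1 lower when adjusted over the list alone (median 1.82, camera adjusted p = 2.06e-05, adjusted p = 0.38 with an estimated correlation). The phosphatase Dusp1 had a log2 fold change of 5.33 and Hspa1a a ratio of 23.4 (7.93 to 114). Of 16 p53 target genes 10 rose and 1 fell, 10 and 1 when adjusted over the list alone (median 1.34, adjusted p = 0.000282, adjusted p = 0.517 with an estimated correlation). Plk2 had a log2 fold change of 4.83 and the cell death gene Bax one of 2.10. Mitochondrially encoded genes fell in all 13 members, 13 when adjusted over the list alone (median -1.63, adjusted p = 1.39e-06, adjusted p = 0.38 with an estimated correlation), from 10.3% and 8.38% to 4.15% and 4.71% of all counts. Of 15 cholesterol synthesis genes 6 rose and 1 fell, 6 and 2 when adjusted over the list alone (median 0.73, adjusted p = 0.139). Sqle had a log2 fold change of 2.20. Of 19 interferon response genes 4 rose and 2 fell, 5 and 2 when adjusted over the list alone (median 0.87, adjusted p = 0.0545). Bst2 had a log2 fold change of 4.35. MHC class II genes fell in 5 of 5 members, 5 when adjusted over the list alone (median -3.85, adjusted p = 0.00134, adjusted p = 0.46 with an estimated correlation). H2-Aa had a log2 fold change of -4.32. Of 10 antimicrobial genes 4 rose and 3 fell, 4 and 3 when adjusted over the list alone (median 0.17, adjusted p = 0.914). The immunoglobulin transporter gene Pigr had a log2 fold change of -5.08 and the serum amyloid gene Saa3 a ratio of 211 (37.8 to 8355), with 99.3% and 92.6% of its counts in the stromal-like cluster of the 2 Lats-deleted libraries.

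Lists of cells outside the epithelium were tested as well. Of 11 stromal and endothelial genes 5 rose and 1 fell, 7 and 1 when adjusted over the list alone (median 3.19, camera adjusted p = 0.0226, adjusted p = 0.565 with an estimated correlation). Decorin (Dcn), a matrix proteoglycan, had a ratio of 223.6 (76.4 to 1085) and was at 633 and 28.6 CPM in Lats-deleted libraries 1 and 2, a call lost without either control library, at adjusted p up to 0.165. Of 5 leukocyte genes 3 fell, 3 when adjusted over the list alone (median -2.97, adjusted p = 0.029, adjusted p = 0.38 with an estimated correlation). Coro1a had a log2 fold change of -4.44, with 52.6% and 60.6% of its control counts in 1 enterocyte-like cluster of each library, and 97.3% and 98.5% of the control counts of Lyz2 were in goblet-like cluster 11. No erythroid gene had enough counts to be tested. With camera 18 of 25 lists passed the threshold, with fry 11, and with an estimated correlation 0. The last count says little about single lists, given the few degrees of freedom. With fry the adjusted p was 0.262 for cell division, 0.238 for stromal and endothelial, 0.204 for tuft and 0.0841 for villus bottom genes. It was 0.0799 for MHC class II, 0.0774 for p53 target and 0.0679 for Paneth genes. The estimated correlation was 0.79 for cell division and 0.504 for enterocyte genes. Both are above the preset 0.01, so their preset adjusted p may be too small. The camera adjusted p of the keratin and actin list went from 7.13e-09 to 0.272, though its estimated correlation of -0.00825 was under the preset 0.01. Of the Y-linked genes 3 of 4 fell, 4 when adjusted over the list alone. Of 4 tested stomach genes 0 passed, 3 higher when adjusted over the list alone (median 5.73), and the list was high in Lats-deleted library 2 alone.

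**Figure D2:**
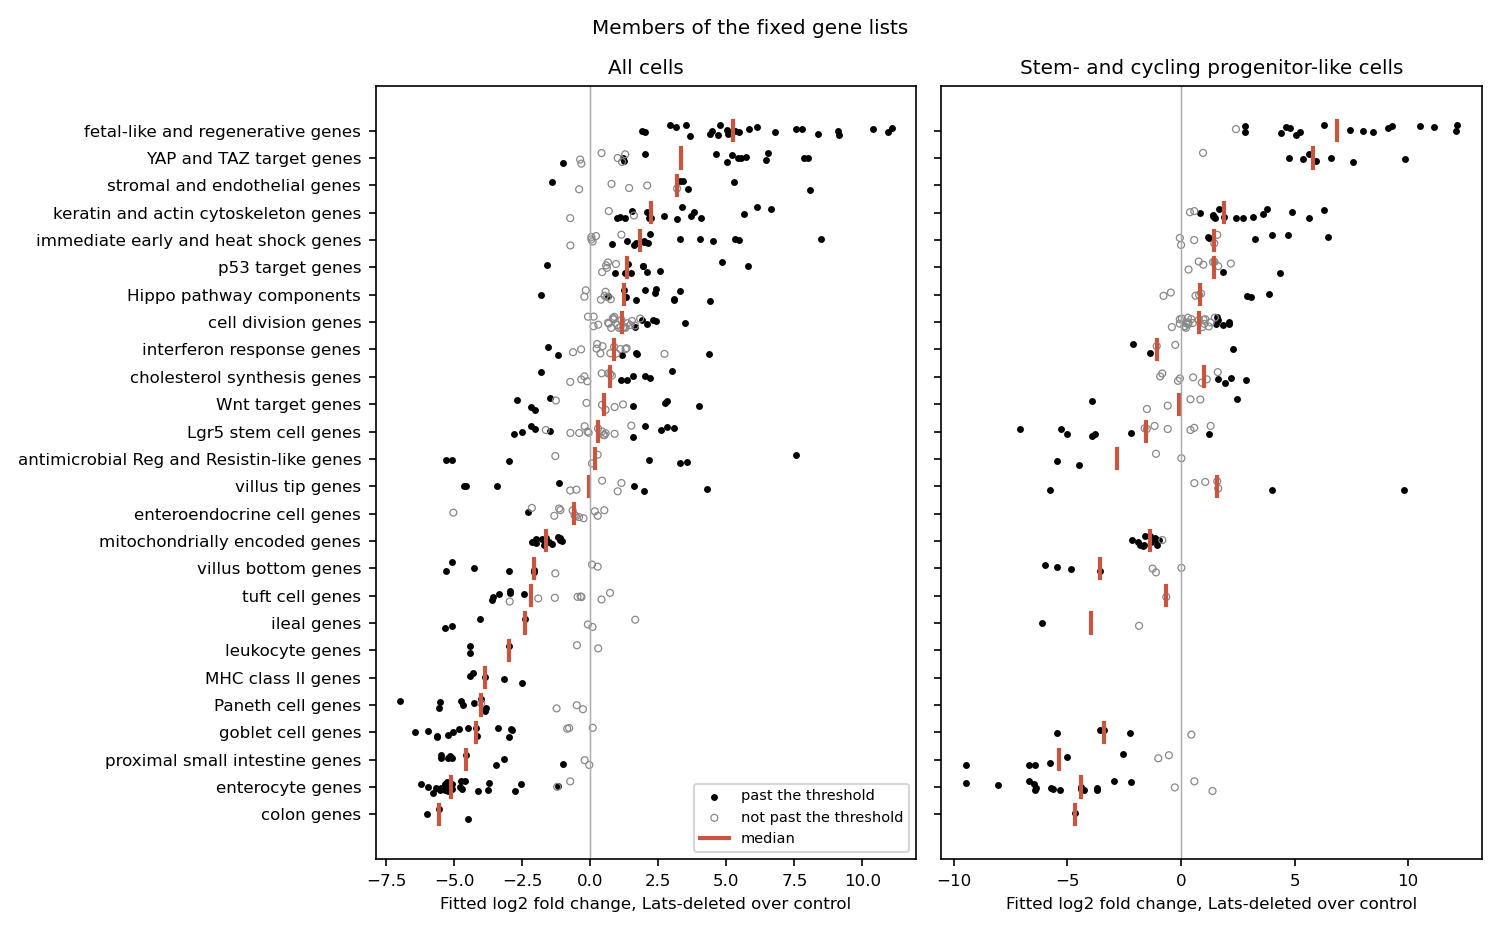
Fitted log2 fold change (Lats-deleted over control) of each tested member of the fixed lists in all cells (left) and in stem- and cycling progenitor-like cells (right); filled points passed the threshold, open points did not, and red bars are list medians. The medians of all cells run from -5.54 for colon genes and -5.13 for enterocyte genes to 5.23 for fetal-like and regenerative genes.

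Cells named enterocyte-like by their cluster made up 75.3% and 73.8% of the control libraries and 5.10% and 1.63% of the Lats-deleted libraries (exact permutation p = 0.333, the smallest 2 against 2 libraries allow). Stem-like cells made up 15.1% and 13.6% against 0.551% and 0.388%, but 6.07% and 6.60% against 3.86% and 5.20% with cells named by marker scores. At a resolution of 2 a stem-like cluster held 47 and 31 control cells against 0 and 4. Another held 32 and 1 against 0 and 0. A cluster of 87 cells, with 42 and 39 control cells against 5 and 1, stayed unnamed. Goblet-like cells made up 6.85% and 7.57% against 0.276% and 0.388%. Regenerative-like cells were 0 of 774 and 1 of 515 control cells, where 0 of 774 allows a share of up to 0.388%, and 60.5% and 25.8% of Lats-deleted cells. Cycling progenitor-like cells were 1.42% and 2.52% against 6.34% and 21.6%. Enteroendocrine-like cells were 0.517% and 1.17% against 0.413% and 1.01%, tuft-like cells 0.517% and 1.17% against 0% and 0.233%, and no cluster was named Paneth-like or leukocyte-like. At a resolution of 2 a cluster of 33 cells was named Paneth-like, with 2.84% and 1.36% against 0.276% and 0.155%, and goblet-like cells were 4.00% and 6.41% against 0% and 0.233%. With marker scores Paneth cells were 1.68% and 1.55% against 2.755% and 1.164% (exact permutation p = 1) and goblet cells 7.49% and 8.74% against 0.138% and 4.34%. Cells of clusters that met no marker rule were 0.258% and 0% against 17.1% and 48.3%, and stromal- or endothelial-like cells were 0% and 0% against 9.78% and 0.621%. All but 489 of the 1289 cells of Lats-deleted library 2 sat in clusters with high counts of stomach genes. Without these clusters the 2 Lats-deleted libraries held 6.39% and 7.77% cycling progenitor-like, 62.4% and 68.1% regenerative-like and 15.1% and 15.5% unnamed cells.

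**Figure D3:**
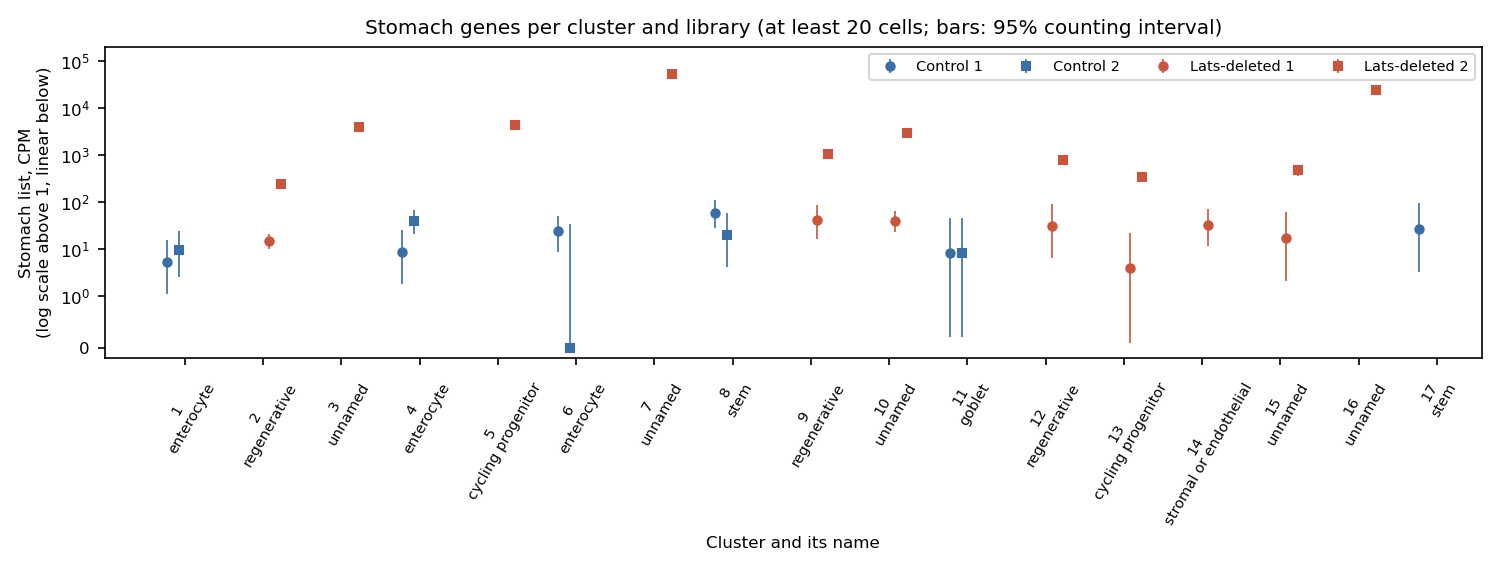
CPM of the list of stomach genes (vertical axis, logarithmic above 1 and linear below) in each cluster with at least 20 cells of a library (horizontal axis), with 95% counting intervals; blue is control, red Lats-deleted, circles library 1 and squares library 2. The stomach genes reach 53000 CPM in cluster 7 of Lats-deleted library 2 and are at 245.2 CPM in its cluster 2.

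**Figure D4:**
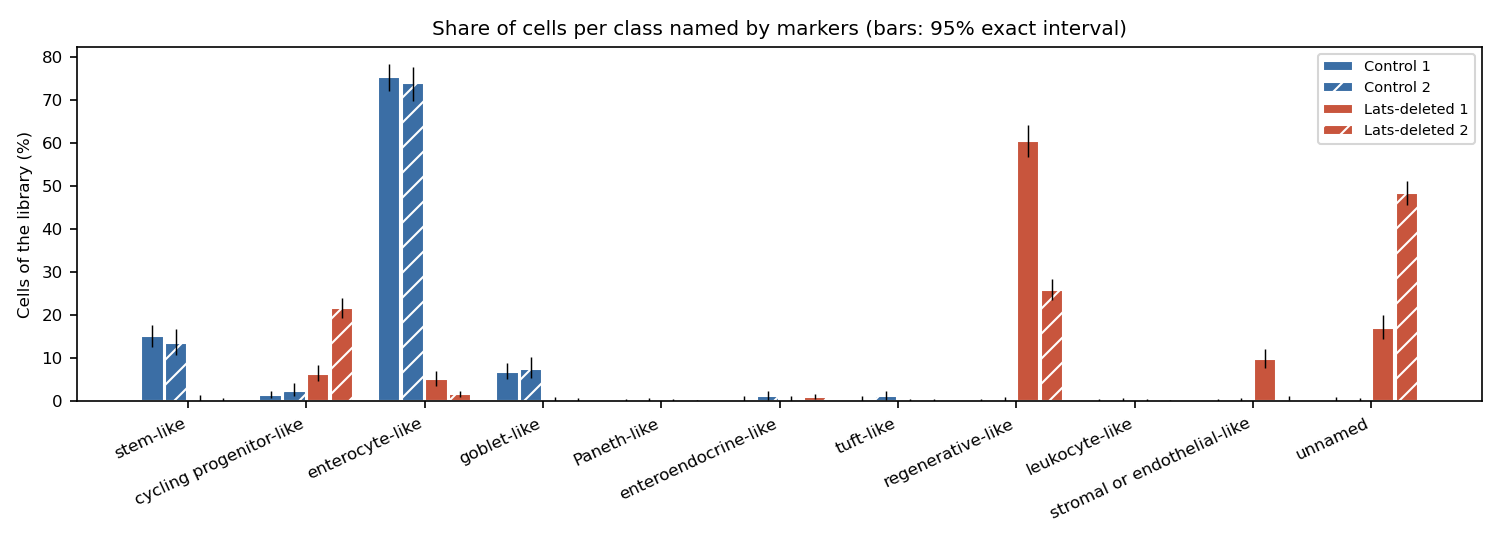
Percent of the cells of each library (vertical axis) in each class named by markers (horizontal axis), with exact 95% intervals; blue bars are control and red bars Lats-deleted libraries, with library 2 hatched. Enterocyte-like cells are 75.3% and 73.8% of control and 5.10% and 1.63% of Lats-deleted cells, and regenerative-like cells 60.5% and 25.8% of the latter.

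With each cell thinned to 1000 counts, Clu was detected in 0.129% and 0.388% of control cells and in 83.7% and 90.3% of Lats-deleted cells (exact permutation p = 0.333). In the enterocyte-like cells of the same libraries the shares were 0% and 0.263% against 8.11% and 19.05%, at the same 1000 counts per cell. Ly6a was detected in 0.258% and 0% against 72.6% and 44.4%, Anxa1 in 0% and 0% against 31.7% and 33.0%, and Ctgf in 0.388% and 0% against 34.7% and 27.2%. The 0 of 515 cells of control library 2 allow up to 0.583% of cells with a count at this depth, which does not limit the cells that express a gene. Cyr61 was detected in 0.517% and 0.388% against 14.7% and 12.7%, the growth factor gene Areg in 1.16% and 0.194% against 24.5% and 12.7%, and Klf6 in 11.6% and 6.99% against 40.4% and 30.1%. Their shares in enterocyte-like cells of the Lats-deleted libraries were at most 14.3%. Muc2 was detected in 8.91% and 10.3% against 0.826% and 0.698%, and the lysozyme gene Lyz1 in 1.55% and 2.14% against 0.275% and 0.543%. Lgr5 was detected in 2.33% and 1.94% against 0.551% and 0.621%, with 1.54% and 1.32% in enterocyte-like control cells. The groups overlapped without thinning, at 4.13% and 3.11% against 3.17% and 2.405% (exact permutation p = 0.667), and at 2000 counts per cell, at 4.42% and 1.17% against 1.09% and 1.335% (exact permutation p = 0.667). Olfm4 was detected in 0.517% and 0.583% against 0% and 0%, or 0.646% and 1.17% against 0.413% and 0.233% without thinning. Shares of Ascl2, Chga and Dclk1 overlapped between the groups (exact permutation p = 0.667, 1 and 0.667).

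**Figure D5:**
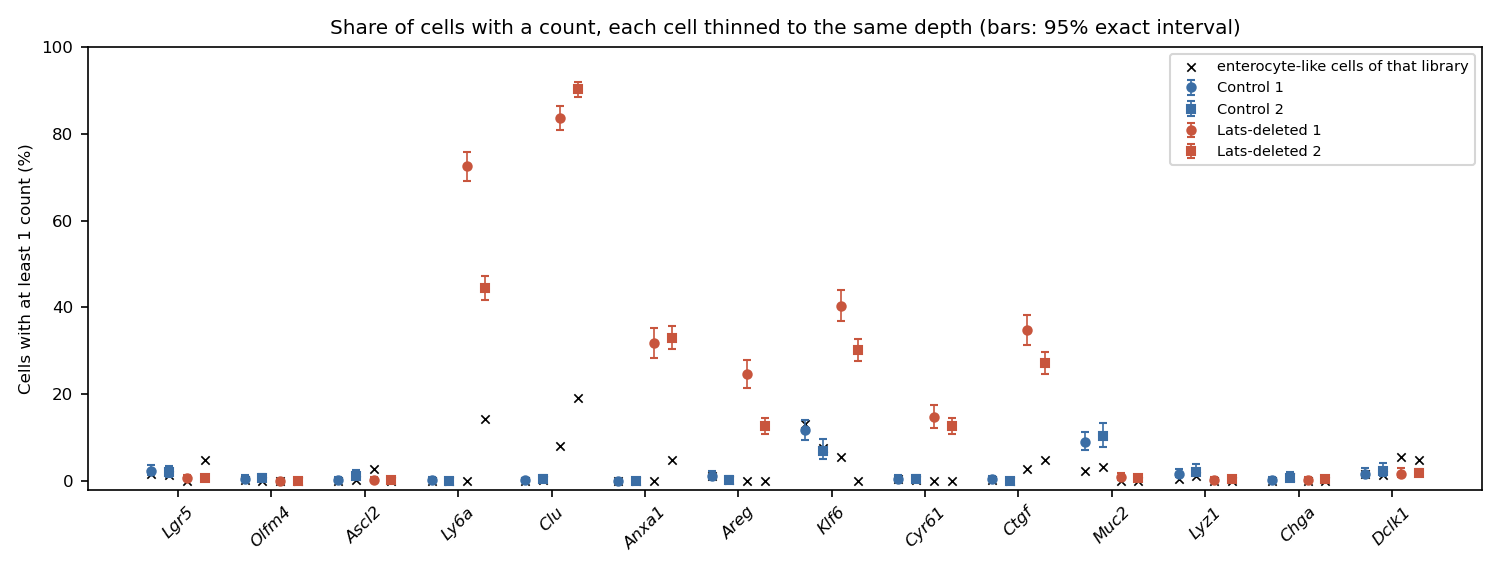
Percent of cells with at least 1 count of each gene (vertical axis), after thinning each cell to 1000 counts, in control (blue) and Lats-deleted (red) libraries with exact 95% intervals; crosses are the enterocyte-like cells of the same library. Clu is detected in 83.7% and 90.3% of Lats-deleted cells and in 0.129% and 0.388% of control cells.

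Stem-like and cycling progenitor-like cells of the Lats-deleted libraries had higher counts of fetal-like and regenerative genes and lower counts of most enterocyte genes tested than control progenitors. The class compares mostly stem-like control cells, 117 of 128 and 70 of 83, with mostly cycling progenitor-like Lats-deleted cells, 46 of 50 and 278 of 283, so differences in cell division and stem cell genes may follow from this make-up. Barcodes of 50 to 299 counts, which hold free RNA, differed in the same direction, with Fabp1 at 1397 and 2935 CPM in the controls against 381 and 23.8 CPM, Apoa1 at 6271 and 6396 against 1488 and 686 CPM, Zg16 at 4922 and 3193 against 1882 and 194 CPM and S100a6 at 82.2 and 251 against 13760 and 15950 CPM. Free RNA may therefore account for part of the changes in this class, goblet genes included. Msln was at 0 in both control libraries and at 1519 and 587 CPM after deletion (at least 94.0-fold higher), the growth-cone protein gene Basp1 at 1330 and 656 CPM (at least 98.2-fold), the stem cell antigen gene Psca at 752 and 594 CPM (at least 80.5-fold), Mal at 779 and 454 CPM (at least 65.3-fold) and Anxa1 at 471 and 532 CPM (at least 65.5-fold). The calcium-binding protein gene S100a6 rose by 8.47 on the log2 scale (SE 0.435, adjusted p = 0.000352) and Clu by 8.004 (SE 0.474, adjusted p = 0.000352). Smoc2, a matricellular stem cell marker, was at 106 and 102 CPM in the control libraries and at 0 and 0.643 CPM after deletion, a ratio of control to Lats-deleted of 189.9 (32.2 to 7683). The control cells lie in clusters 8, 17 and 19 while the Lats-deleted cells lie mostly in clusters 13 and 5. Cluster 5 holds 240 cells of Lats-deleted library 2 and 1 cell of library 1 and is 1 of the clusters with high counts of stomach genes.

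In this class 1044 of 4977 genes tested passed the threshold, 472 higher and 572 lower, and 1768 had an unadjusted p under 0.05. Of 18 fetal-like and regenerative genes 17 rose, 18 when adjusted over the list alone, with a median log2 fold change of 6.86, or 5.32 with genes at 0 counted at their bound (camera adjusted p = 9.7e-16, adjusted p = 0.241 with an estimated correlation). Of 8 YAP and TAZ target genes 7 rose, 7 when adjusted over the list alone (median 5.80, or 5.50 at the bounds, adjusted p = 9.01e-08, adjusted p = 0.241 with an estimated correlation), with Ctgf at a ratio of 173 (31.0 to 6855) and F3 at 98.4 (17.6 to 3896). Of 8 Hippo components 3 rose, 3 when adjusted over the list alone (median 0.84, adjusted p = 0.029, adjusted p = 0.241 with an estimated correlation). Keratin and actin genes rose in 15 of 17 members, 15 when adjusted over the list alone (median 1.91, adjusted p = 9.64e-09, adjusted p = 0.241 with an estimated correlation). Krt7 had a log2 fold change of 6.28. Of 14 Lgr5 stem cell genes 1 rose and 6 fell, 2 and 9 when adjusted over the list alone (median -1.55, adjusted p = 0.00303, adjusted p = 0.241 with an estimated correlation). Lgr5 went from 71.0 and 78.2 to 0 and 5.79 CPM (log2 fold change -3.91, SE 0.608, adjusted p = 0.00439), a call lost without either control library, with adjusted p between 1.18e-05 and 0.112 over the alternatives. The chloride cotransporter gene Slc12a2 fell by 2.19. Of 6 Wnt target genes 1, Ccnd1 with a log2 fold change of 2.47, rose and 1, Lgr5, fell, 1 and 1 when adjusted over the list alone (median -0.09, adjusted p = 0.837).

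Of 20 enterocyte genes 17 fell in the progenitor class, 17 when adjusted over the list alone, with a median log2 fold change of -4.41 (camera adjusted p = 3.45e-09, adjusted p = 0.241 with an estimated correlation). Rbp2 had a log2 fold change of -6.45. Proximal genes fell in 6 of 8, 7 when adjusted over the list alone (median -5.39, adjusted p = 1.96e-05, adjusted p = 0.241 with an estimated correlation), villus bottom genes in 4 of 7, 4 when adjusted over the list alone (median -3.57, adjusted p = 0.000565, adjusted p = 0.241 with an estimated correlation), and goblet genes in 4 of 5, 4 when adjusted over the list alone (median -3.41, adjusted p = 0.00303, adjusted p = 0.241 with an estimated correlation). Of 27 cell division genes 6 rose, 10 when adjusted over the list alone (median 0.78, adjusted p = 0.000565, adjusted p = 0.264 with an estimated correlation). Tubb5 had a log2 fold change of 2.11. Immediate early and heat shock genes rose in 6 of 11, 9 when adjusted over the list alone (median 1.46, adjusted p = 0.00037, adjusted p = 0.241 with an estimated correlation). Junb had a log2 fold change of 4.01. Of 9 p53 targets 2 rose, 2 when adjusted over the list alone (median 1.47, adjusted p = 0.00273, adjusted p = 0.329 with an estimated correlation). Of 12 cholesterol synthesis genes 4 rose, 4 when adjusted over the list alone (median 1.03, adjusted p = 0.0433, adjusted p = 0.536 with an estimated correlation). Sqle had a log2 fold change of 2.86. Mitochondrially encoded genes fell in 12 of 13, 13 when adjusted over the list alone (median -1.37, adjusted p = 3.09e-06, adjusted p = 0.304 with an estimated correlation). Villus tip genes (2 higher and 1 lower of 7, adjusted p = 0.0604) and interferon response genes (1 higher and 2 lower of 5, adjusted p = 0.304) did not pass as lists. The count of genes was 617 with DESeq2, 642 with clusters at a resolution of 2, 592 without control library 1 and 1581 without the clusters with high stomach genes, and the calls of Smoc2 and of S100g, a calcium-binding protein gene among the 8 largest decreases, were lost with classes from marker scores.

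The few enterocyte-like cells of the Lats-deleted libraries, 37 and 21 cells against 583 and 380, differed from control enterocyte-like cells in 10 of 5723 genes tested with edgeR, 3 higher and 7 lower, and 439 had an unadjusted p under 0.05. Clu rose by 5.62 on the log2 scale (SE 0.807, adjusted p = 8.66e-06), S100a6 by 3.20 (SE 0.310, adjusted p = 1.01e-10) and the mitochondrial import factor gene Grpel2 by 1.67 (SE 0.261, adjusted p = 4e-05). Zg16 was lower, at a ratio of control to Lats-deleted of 14.6 (4.98 to 71.1), as were the metallothioneins Mt1 and Mt2, Cd74, Pck1, Sgk1 and Gstm1, with log2 fold changes from -2.77 to -1.37. S100a6 and Clu were also abundant in barcodes of 50 to 299 counts, at 13760 and 15950 CPM and at 3701 and 4576 CPM in the Lats-deleted libraries, and Zg16 was at 4922 and 3193 CPM in those of the controls. Lats1 was at 20.6 and 40.3 CPM in the control and 23.4 and 37.1 CPM in the Lats-deleted libraries (log2 fold change -0.04, SE 0.860, adjusted p = 1), and its sign changed in 4 of 9 alternatives. None of the 28 enterocyte genes passed, 2 lower when adjusted over the list alone (median -0.19, adjusted p = 0.306). Camera called villus bottom genes higher (median 0.57, 0 of 8 past the threshold, 3 when adjusted over the list alone, adjusted p = 0.0098), goblet genes lower (1 of 8, 2 when adjusted over the list alone, adjusted p = 0.0098) and MHC class II genes lower (1 of 5, 4 when adjusted over the list alone, adjusted p = 0.0107). With an estimated correlation the adjusted p was 0.58 for each of the 3 lists. The count of genes was 4 with DESeq2, 5 with thinned libraries, 24 with classes from marker scores, 71 without a filter on low counts, 6 and 19 without control library 1 or 2, and 52 and 24 without Lats-deleted library 1 or 2, and 9 of the 10 calls were lost under at least 1 alternative.

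Whether the effect differed between the classes was tested as the difference of the log2 fold changes, progenitor minus enterocyte-like, in 6020 genes. Of these 453 passed the threshold, 193 with a positive and 260 with a negative difference, and 1303 had an unadjusted p under 0.05. The enterocyte-like cells of Lats-deleted library 1 may come from a male animal, as given below. Lats1 had a log2 fold change of -0.04 in the enterocyte-like class. The Lats-deleted sums of this class held 91193 and 55004 counts, too few for Lats1 to show whether these cells carried the deletion. Given the possible male origin in library 1, the 453 genes may largely restate the progenitor change and not a difference of Lats effects. Among the 453 genes, 345 also passed within the progenitor class, all 345 with the sign of the progenitor change, and 1 passed within the enterocyte-like class. The difference contains the progenitor change, so the shared sign is no separate support. Enterocyte genes gave 23 negative and 1 positive difference among 28 tested, with Slc5a1 at -7.76 (SE 0.778, adjusted p = 7.83e-06) and Fabp1 at -6.79 (SE 0.700, adjusted p = 1.03e-05). Keratin and actin genes gave 12 positive differences of 17 tested and 0 negative, with Krt7 at 4.40 (SE 0.754, adjusted p = 0.00132), and fetal-like and regenerative genes 8 of 19 and 0, with S100a6 at 5.54. The difference for Clu was 2.68 (SE 1.19, adjusted p = 0.198). Villus bottom genes gave 4 negative differences of 8, with Reg1 at -5.25, and mitochondrially encoded genes 4 of 13. Villus tip genes went mostly the other way, with 5 positive and 1 negative difference of 11. The count was 211 without control library 1, 287 without control library 2 and 718 without Lats-deleted library 2, and the control and Lats-deleted progenitors come from different clusters, as given above.

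Goblet-like and Paneth-like cells could not be compared by cluster, with 2 and 5 such cells in the Lats-deleted libraries. With cells named by marker scores, 71 and 53 control and 21 and 71 Lats-deleted cells gave 334 of 2447 genes past the threshold, 151 higher and 183 lower. The make-up of this class differed, with 58 and 45 control and 1 and 56 Lats-deleted cells named goblet and the others Paneth.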

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

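The tests of genes in all cells and in enterocyte-like cells, the test of the class by genotype term and the fit of thinned libraries were planned. All other tests in this part were chosen after the results were seen.

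A difference between groups drew attention to the progenitor and enterocyte-like classes, whose changes between the libraries differed in 453 genes by a test of the difference itself. The enterocyte-like cells behind it, 37 in Lats-deleted library 1 and 21 in library 2, differed from control enterocyte-like cells in 10 of 5723 genes. Against undeleted cells of the same animal in library 1 stand the Y-linked genes, at 120.6 CPM (95% counting interval 60.2 to 215.8) in these cells and at 30.93 CPM (25.35 to 37.38) in the other cells of the library without stem-like cells. Xist was at 11 CPM (0.282 to 61.1) there and at 658.9 CPM (632 to 686.5) in the other cells, so cells from a male animal may account for this group in library 1. In that case the 453 genes do not measure a difference of Lats effects between the classes. None of the 37 cells had a barcode found in a control library, as 7.06% of the regenerative-like cells did, which gives no sign of barcodes read in the wrong library, and how such cells came there stays open. In library 2 the 21 cells are too few, with Xist at 145 CPM (62.8 to 286.6) against 509.7 CPM and the Y-linked genes at 18.18 CPM (0.460 to 101.3), and cells from a male animal and undeleted cells of the same animal cannot be told apart.

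Stomach genes such as Tff1 were abundant in 1 library. The list of stomach genes was at 18.08 and 17.91 CPM in the control libraries, at 21.61 CPM in Lats-deleted library 1 and at 0.995% of all counts in library 2. Free RNA is argued against, since the level in cluster 7 of that library was 216 times the level in its regenerative-like cluster 2, and so is an effect of the deletion in both libraries, since library 1 was at 1.20 times the higher control. Cells of the stomach in the tissue taken stay open, as does an effect of the deletion in library 2 alone. Cdx2, an intestinal transcription factor gene, was at 21.8 CPM (17.2 to 27.1) in the clusters with stomach genes and at 63.2 CPM (51.1 to 77.4) in the regenerative-like cells. The interval does not place it under 0.5 of the lower bound that stomach cells were set to need. The test pooled clusters with the stomach list from 3780 CPM in cluster 3 to 53000 CPM in cluster 7. It therefore cannot decide for clusters 7 and 16 alone, which held cells of library 2 only. Genes highest in them against other cells included Gkn2, Gkn1 and Tff1 in cluster 7 and Pgc, Muc6 and Tff2 in cluster 16. The explanations cannot be told apart by this test.

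A signal outside the main measurement was found in barcodes of 50 to 299 counts, where Tff1 was at 6691 CPM in Lats-deleted library 2, at 96.3 CPM in library 1 and at 3.42 and 70.4 CPM in the controls.

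The 3869 genes past the threshold in all cells were weighed against sex, depth and other cell types. Without genes of chromosomes X and Y the count was 3802, but sex differs between the groups in every library by Xist and the Y-linked genes, so sex and Lats deletion cannot be told apart for autosomal genes by this design. With every library thinned to one total the count was 3593, within 1.5 times, which argues against the lower depth of the controls as the whole cause. Without the clusters with stomach genes and the stromal-like cluster it was 5171, which argues against these cells as the whole cause. The make-up of the cells was not tested as a cause. Enterocyte-like cells were 583 of 774 and 380 of 515 control cells, and 37 of 726 and 21 of 1289 Lats-deleted cells. Within enterocyte-like cells 10 of 5723 genes passed, though few Lats-deleted cells entered that fit. Only the Lats-deleted mice carried Cre, per the labels, so an effect of Cre itself cannot be told apart from that of the deletion. An effect of the deletion itself remains a hypothesis beside sex, Cre and the make-up of the cells.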

How the results depend on the processing

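The fits without clusters with stomach genes, without stromal-like cells together with these, without genes of chromosomes X and Y, and of the class by genotype term without a library were chosen after the data were seen, and the other alternatives before. The count of genes in all cells stayed within 1.5 times of 3869 under the alternatives other than leaving out a library, at 3172 with DESeq2 and 5171 at the ends, and ranged from 1228 to 5387 with each library left out. The progenitor count of 1044 was 617 with DESeq2, 642 at a resolution of 2 and 1581 without clusters with stomach genes, and 592 to 1364 without a library. The enterocyte-like count of 10 was 4 with DESeq2, 5 with thinned libraries, 24 with marker scores, 27 with a replicate term, 71 without a filter on low counts, and 6 to 52 without a library. Minimums of 2000 counts and a limit of 15% mitochondrial counts left under 20 enterocyte-like cells in a library and were not run, nor were the goblet and Paneth fits other than marker scores. The class by genotype count of 453 was 211 to 718 without a library. Of the gene lists, 18 in all cells became 0 with an estimated correlation and 11 with fry, 14 in progenitors became 0 with an estimated correlation, and 3 in enterocyte-like cells became 0 with either and 0 to 4 without a library. With an estimated correlation few lists could pass, given the few degrees of freedom, and the causes of the other changes were not tested.

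Differences of shares (Lats-deleted minus control mean, percentage points) larger than the SD between libraries changed sign with marker scores for tuft-like cells, at 0.843, and unnamed cells, at -0.2889, and without thinning for Ascl2, at 0.1415. Without a library they ran from -1.049 to -0.4004, from 16.95 to 48.2 and from -0.9497 to -0.04308. Smaller differences, of enteroendocrine-like cells, of stem-like with cycling progenitor-like cells, and of Chga and Dclk1, also changed sign, the second from -1.906 to 13.11 with marker scores and 8.876 at a resolution of 2, and Dclk1 from -0.247 to 2.558 without thinning. The enterocyte-like difference of -71.2 was -67.0 with marker scores and -68.1 from 2000 counts per cell. The Lgr5 difference was -0.834 without thinning in place of -1.55, that of Ly6a 74.2 in place of 58.4 and that of Clu 92.8, or 93.2 with 2000 counts, in place of 86.8, where deeper cells by construction hold more genes. Of 1126 values of 87 genes followed in all cells, apart from those without a library, 1121 kept direction and side, 3 lost the call and 2 changed sign, and of 348 values without a library 319, 27 and 1, with 1 gained call. In progenitors 361 of 378 kept both, and 128 of 140 without a library. In enterocyte-like cells 89 of 110 kept both, with 16 lost calls and 3 changes of sign, and 44 of 53 without a library. For the class by genotype term 28 of 30 and 38 of 40 kept both. The Cdx2 fold in all cells changed sign, to 0.158 without stomach-gene and stromal-like clusters and 0.079 without stomach-gene clusters, and ran from -0.994 to 0.287 without a library. The Lats1 fold in enterocyte-like cells was 0.255 with marker scores, 0.001 at a resolution of 2 and 0.028 with a replicate term, and ran from -0.397 to 0.196 without a library. In simulated counts 2-fold changes were rarely recovered in any class, so changes of this size may be missed.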

Other observations

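The genes, lists and counts of cells in this part were chosen after values had been seen, and no explanation was tested for them. Of 15 intestinal transcription factor genes, a list without a list test, 1 rose in all cells and 8 fell, 1 and 9 when adjusted over the list alone (median log2 fold change -1.0). Cdx1, a homeobox gene of the intestine, fell by 3.93 on the log2 scale (SE 0.248, adjusted p = 0.000202), from 94.9 and 106 to 7.18 and 6.01 CPM. The nuclear receptor gene Hnf4g fell by 2.97 (SE 0.366, adjusted p = 0.00162) and Hnf4a by 1.61 (SE 0.251, adjusted p = 0.00404), the latter a call lost without control library 1, at 0.0802, with adjusted p from 9.46e-16 over the alternatives. Cdx2 was at 76.5 and 79.1 CPM in the controls and at 95.9 and 39.0 CPM after deletion (log2 fold change -0.21, SE 0.411, adjusted p = 0.732).

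In all cells Wnt7b rose by 6.85 on the log2 scale (SE 0.637, adjusted p = 0.000552) and Wnt7a by 6.06 (SE 0.848, adjusted p = 0.00264), the latter with 4 counts in control library 1 and 0 in library 2 and a range of 5.21 to 11.63 over the alternatives, and Wnt7b had 81.8% and 51.3% of its counts in regenerative-like cluster 2 of the Lats-deleted libraries. The EGF-family ligand gene Hbegf rose by 3.87 (SE 0.322, adjusted p = 0.000402) and the urokinase receptor gene Plaur by 6.32 (SE 0.305, adjusted p = 0.000183).

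Of 15 tested pancreatic enzyme genes 12 rose, 12 when adjusted over the list alone, among them chymotrypsinogen (Ctrb1) at 0.708 and 0 CPM in the controls and 170 and 144 CPM after deletion. In Lats-deleted library 1, 2 cells held 90% of the 2542 counts of these genes, and in library 2, 1 cell held 90% of 3531 counts. Of the 1923 genes higher in all cells, 14 had 90% of their counts in at most 5 cells in each Lats-deleted library.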
